A study of Mus musculus with 23 samples.

How the data were processed

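RNA-seq values of 23 libraries from sorted splenic CD4+ T cells were used, in 6 groups formed by 2 lineages and 3 activation states. Per the labels' protocols, TCRβ+ CD4+ cells negative for NK-1.1, CD1d tetramer and CD8α were sorted in 2 rounds of FACS as Foxp3+ or Foxp3-, RNA was extracted with TRIzol, amplified (SMARTer) and poly(A)-selected, and TruSeq libraries were sequenced as paired ends. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to GRCm38 with TopHat2 2.0.11 and Bowtie2 2.2.2, handled with SAMtools 0.1.19 and counted per gene with HTSeq 0.6.1p1. The deposited table holds, per the labels, a signal for each gene and library in the form of normalised counts. The tool that normalised them, the annotation version and the strand setting of the counting are not given in the sources used here. No columns of per-sample values were left unused.

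The deposited signal was checked against whole reads. Dividing each library by its smallest step gave whole numbers for 100% of values (tolerance 0.001 of a read), and the recovered size factors equalled the median-of-ratios factors of those reads, so the values are read counts divided by a factor per library. Recovered depth ran from 26.7 M to 51.7 M reads. The table holds 17478 genes, each with at least 46 reads in all libraries together. Gene IDs were matched to GENCODE M21 on GRCm38 for 17223 genes, and 255 kept their ID without a symbol.

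The main test was limma 3.58.1 in R 4.3.3 (trend and robust variance) on log2(normalised count + 1), with 1 coefficient per group over all 6 groups. Genes had to reach a value of 10 in at least 3 libraries, which left 15704 and removed 1774. Contrasts were activation (CD49b-negative CD44-high against CD62L-high) and the CD49b step in each lineage, Treg against Tconv in each of the 3 states, and the difference of each step between lineages. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05 on the adjusted p. Replicate numbers were not used to pair samples, since the labels do not say that a number marks a shared animal. The design, the comparisons and the 27 gene lists were fixed before the data were examined. So were the alternatives, except leaving out both libraries farthest from their groups and quantile normalisation of the list tests.

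Genes were named by a rule: the gate genes, then in each direction the 10 called genes with the largest log2 fold change, no overlap of library values and a mean of at least 50 in the higher group, leaving out antigen receptor segments, predicted genes and pseudogenes. Up to 4 called members with the smallest p followed for each list with at least 3 called, and the 5 largest in each direction for the interactions. Members named because they moved against their list or were its only call, T cell receptor γ, immunoglobulin and haemoglobin genes, and further interaction genes were chosen after their values were seen. A few genes that this rule names are not reported here. Where a group had 0 reads, the floor was 3 reads over the group.

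The lists covered Treg signature, Tconv-high, effector Treg, naive and quiescence, integrin, chemokine receptor, egress, Th1 and cytotoxic, Th2, Th17, Tfh, Tr1, suppressive, checkpoint and costimulatory, cell cycle, T cell receptor signal, heat shock, interferon, glycolysis and cholesterol synthesis genes, and markers of platelets, NK and NKT cells, B cells, myeloid cells, basophils and mast cells, CD8 and γδ T cells, and erythroid cells. They were written from general knowledge, and members below the filter were not tested. Each was tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. The last asks whether the list shifted in a single direction, without reference to other genes. P-values were adjusted over the 243 tests, and members were also adjusted over the list alone. A pair of plasmacytoid dendritic cell lists and a list of B lineage genes were added later. Principal components were computed on all genes tested.

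The count test was edgeR 4.0.16 (quasi-likelihood) on recovered reads, which called 4845, 876, 4387 and 1836 genes for activation and the CD49b step in Treg and then in Tconv. It called 3475, 3703 and 4439 for lineage in the CD62L-high, CD49b-negative and CD49b-positive states, and 227 and 1235 for the differences in the CD49b and activation steps. Further alternatives were DESeq2 1.42.0, pseudocounts of 0.5 and 8, no filter, a filter at 50, quantile and TMM normalisation, library weights, only the groups compared, a replicate block, and leaving out each library. Figures and tables used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GC content and length were known for 15506 of the genes tested (98.7%).

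The fits were tested on simulated data with the depths of these libraries and a spread for each gene that all libraries shared. In them 200 genes with a mean of at least 50 were changed, 100 of them 2-fold and 100 4-fold. Of the 2-fold changes, 67% and 73% were called for activation and the CD49b step in Treg, 67% and 72% in Tconv, 68%, 73% and 71% for lineage in the CD62L-high, CD49b-negative and CD49b-positive states, and 39% and 54% for the differences in the CD49b and activation steps. Of the 4-fold changes, 97%, 95%, 99%, 95%, 94%, 96%, 93%, 88% and 86% were called in the same order, with 6 to 13 false calls. A list in which 10 of 15 members were changed was called in all 9 comparisons, and 0 of 100 unchanged lists were in each. Simulated genes were drawn independently, so the check cannot show false list calls that arise from correlated genes. No simulated library had a larger spread than others, so the rates do not cover data with libraries that stand apart from their groups.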

Results

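Messenger RNA was sequenced from CD4+ T cells sorted from the spleens of 8-week-old male mice of the Foxp3GFP strain on the C57BL/6 background. In these mice green fluorescent protein reports Foxp3, the transcription factor of regulatory T cells (Treg), which restrain immune responses. Treg (Foxp3+) and conventional T cells (Tconv, Foxp3-) were each sorted in 3 states, and NK-1.1+, CD1d tetramer-binding and CD8α+ cells were gated out. CD62L-high CD44-low cells formed the naive Tconv and resting Treg groups. CD44-high cells, named Teff in Tconv and aTreg in Treg, were divided by surface CD49b, the integrin α2 subunit encoded by Itga2. The 23 libraries thus fell into 6 groups of 4, except naive Tconv with 3, because the RNA of its replicate 3 was degraded per the design text. Libraries held from 26.7 M reads (CD49b-negative Teff replicate 2) to 51.7 M (CD49b-negative aTreg replicate 3), and 15590 to 16879 of the 17478 genes had at least 1 read.

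Levels are given as normalised read counts, mean ± SD over the libraries of a group (n = 4, and n = 3 for naive Tconv). Log2 fold changes are given ± SE from limma on log2(normalised count + 1), a scale that understates the change of low genes. A gene is called higher or lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg over the 15704 genes tested). The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which can include technical spread. Unless stated otherwise, all library values of one group lay above all of the other for each gene named with a fold change. A gene with 0 reads in one group is given as at least the fold that a floor of 3 reads over that group allows, and one with 1 to 3 reads as a ratio with its 95% counting interval. Floors and intervals cover counting error only. Gene lists were fixed before the data were examined and tested with camera, which compares a list with all other genes at a preset correlation of 0.01 (Benjamini-Hochberg over 243 tests). Called lists given without a further p also held when the correlation was estimated from the data. Some lists share members, such as Ctla4 and Entpd1 in the Treg signature and suppressive lists, so calls of such lists are not independent.

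The genes of 3 sorted markers followed the gates. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) averaged 44000 ± 9389, 46550 ± 5397 and 56770 ± 2725 normalised counts in resting, CD49b-negative and CD49b-positive Treg. The matching Tconv groups held 69.1 ± 18.5, 15.1 ± 8.59 and 13.0 ± 15.6. Itga2 (ENSMUSG00000015533, chromosome 13, 114833081 to 114932100) reached 1125 ± 268 in CD49b-positive Teff and 568.6 ± 48.7 in CD49b-positive aTreg. It averaged 98.6 ± 54.1 and 46.4 ± 20.7 in the CD49b-negative groups, 13.8 ± 9.35 in naive Tconv and 13.2 ± 12.9 in resting Treg. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665) was at 895.7 ± 152 in naive Tconv and 1292 ± 341 in resting Treg, and at 10100 ± 433 to 16580 ± 2694 in the CD44-high groups. Because these genes encode the sorted proteins, their differences check the labels and are not findings of the comparisons.

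**Figure D1:**
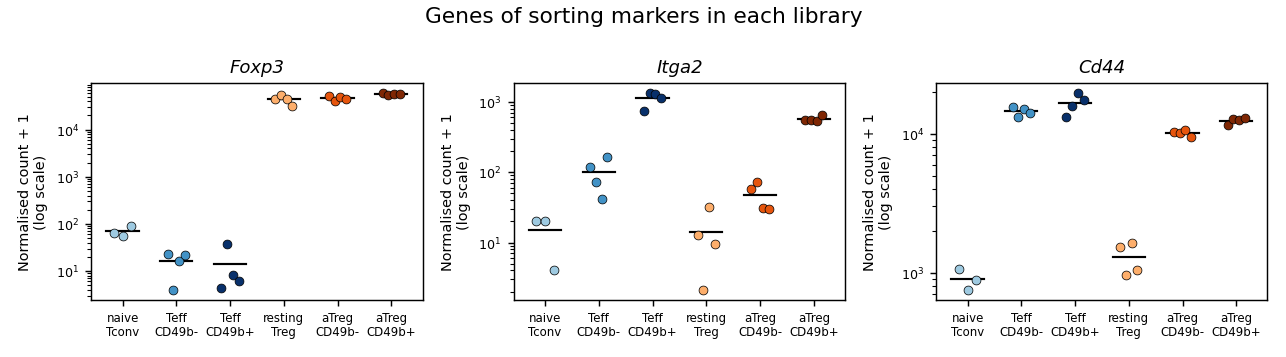
Normalised read count plus 1 (log axis) of Foxp3, Itga2 and Cd44 in each of the 23 libraries, arranged by the 6 groups, with points for libraries and a line at each group mean. Foxp3 means lie at 44000 to 56770 in the Treg groups and at 13.0 to 69.1 in the Tconv groups, and Itga2 means at 568.6 and 1125 in the CD49b-positive groups.

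The first principal component of the log2 values held 36.7% of the variance and the second 22.6%. Resting Treg replicate 2 and CD49b-positive Teff replicate 1 lay apart from the other libraries of their groups. Mitochondrial transcripts took 1.36% ± 0.0784 of reads in naive Tconv, and 1.44% ± 0.250 and 1.19% ± 0.0810 in CD49b-negative and CD49b-positive Teff. They took 0.749% ± 0.218, 0.932% ± 0.355 and 0.853% ± 0.105 in resting, CD49b-negative and CD49b-positive Treg.

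**Figure D2:**
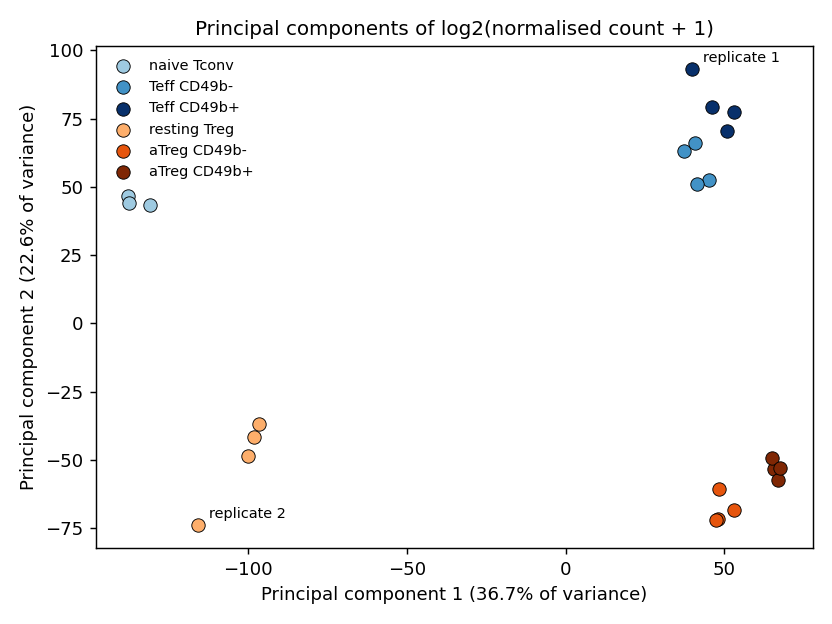
Scores of the 23 libraries on the first (36.7% of variance) and second (22.6%) principal components of the log2 values, with points for libraries and colours for the 6 groups. Resting Treg replicate 2 and CD49b-positive Teff replicate 1 are marked as the libraries farthest from their groups.

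The comparison of resting Treg with naive Tconv asked how the lineages differed in the CD62L-high CD44-low state. Lrrc32 (ENSMUSG00000090958, chromosome 7, 98489283 to 98502181), whose product GARP holds latent TGF-β on the Treg surface, reached 41540 ± 8946 in resting Treg, a log2 fold change of 13.27 ± 0.54 over naive Tconv. Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), the IL-2 receptor α chain, averaged 43670 ± 8246 against 99.2 ± 32.9 (8.80 ± 0.24, adjusted p = 1.79e-16, limma). Also higher were Coro2a (9.34 ± 0.33), Sdc4 (9.51 ± 0.70), Ntn4 (8.40 ± 0.42), the ectonucleotidase Entpd1 or CD39 (8.37 ± 0.44), Lamc1 (ratio 3510, 972 to 29000) and Fam160a1 (ratio 1480, 265 to 58400). Pdlim4 (ENSMUSG00000020388, chromosome 11, 54054928 to 54069014) averaged 42.2 ± 14.8 against 4798 ± 362 (-6.86 ± 0.52). Ggt5 (-6.81 ± 0.52), App (-6.77 ± 0.82), Rnf32 (-6.58 ± 0.55), Atp8b4 (-6.69 ± 1.19) and Klrd1 (-7.93 ± 0.92) were also lower. Pcsk1 was at least 160-fold lower, Dmbt1 at least 159-fold lower and Wnt5b lower by a ratio of 1130 (203 to 44800). Dmbt1 was not called under DESeq2. In total 2094 genes were higher in resting Treg and 1567 lower, of which 1083 and 746 by at least 2-fold. With only the compared groups in the fit, 1241 were higher and 589 lower.

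All 19 genes of the Treg signature were higher, and also when adjusted over the list alone, among them Ctla4 (5.28 ± 0.12), Socs2 (6.83 ± 0.18) and Tnfrsf4 or OX40 (5.45 ± 0.15). The list was called by camera (adjusted p = 6.47e-38). Of 10 genes known to be higher in Tconv, 9 were lower, 9 also over the list alone (adjusted p = 4.5e-13), with Dapl1 (-4.22 ± 0.24), Cd40lg (-2.71 ± 0.16) and Id2 (-2.21 ± 0.09). Of 12 suppressive molecules 11 were higher (11 over the list alone, adjusted p = 3.26e-16), and of 22 effector Treg genes 18 (18, adjusted p = 4.46e-15). Of 18 checkpoint and costimulatory receptors 12 were higher and Cd28 was lower (12 and 1, adjusted p = 3.03e-12). Among chemokine receptors 7 of 15 were higher and 2 lower (7 and 2, adjusted p = 0.000525): Ccr6 was at least 316-fold higher, Ccr9 and Cxcr5 rose by 3.82 ± 0.21 and 2.70 ± 0.16, and the lymph node homing receptor Ccr7 fell by 1.29 ± 0.11. The naive and quiescence list was lower (10 of 19 lower, 4 higher, the same over the list alone, adjusted p = 2.04e-05), with Lef1 (-1.26 ± 0.10) and Tcf7 (-1.70 ± 0.15) lower, and Foxo1, Id3 and Klf2 among those higher. Th2 (5 of 8, 5 alone, adjusted p = 2.5e-05), Th17 (5 of 10, 5 alone, adjusted p = 0.00268) and Tr1 genes (7 of 10 higher and Cd226 lower, 7 and 1 alone, adjusted p = 0.000655) were also called higher. Beside them, genes of CD8 and γδ T cells were called higher (adjusted p = 0.000104), through the T cell receptor γ constant genes alone. Tcrg-C1 averaged 1030 ± 250 and Tcrg-C4 688.4 ± 101 in resting Treg, the latter at least 729-fold higher, but these near-identical genes can share reads. No cell cycle gene was called (adjusted p = 0.904). Integrins, Tfh, T cell receptor signal and cholesterol synthesis genes were called higher with the preset correlation, but their adjusted p was 0.16, 0.0851, 0.0641 and 0.164 with an estimated correlation. Egress, Th1 and cytotoxic, heat shock, interferon, glycolysis, platelet, NK, B, myeloid, basophil and mast, and erythroid genes were not called as lists.

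**Figure D3:**
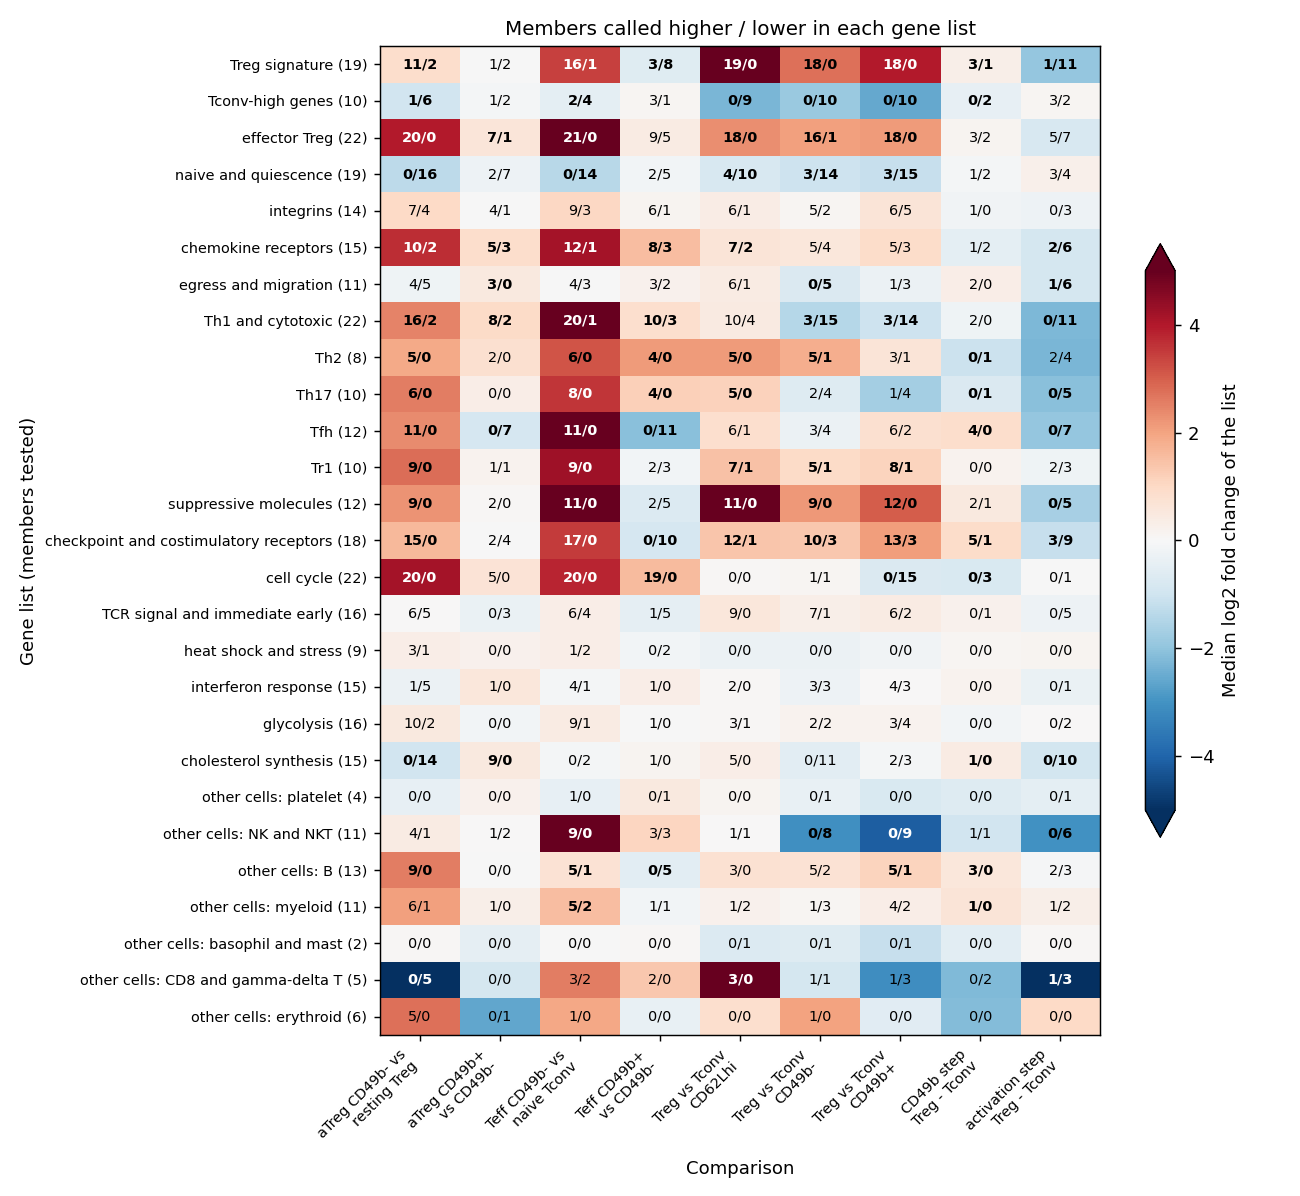
Heat map of the 27 gene lists (vertical) in the 9 comparisons (horizontal), coloured by the median log2 fold change of the list on a scale from -5 to 5 and printed with the number of members called higher/lower; bold marks lists called by camera with both the preset and the estimated correlation. All 19 Treg signature genes are higher in resting Treg than in naive Tconv, and 14 of 15 cholesterol synthesis genes are lower in CD49b-negative aTreg than in resting Treg.

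CD49b-negative Teff were compared with naive Tconv to describe activation in the conventional lineage. The chemokine receptor Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269) rose from 23.9 ± 14.5 to 23470 ± 1432 (10.09 ± 0.32, adjusted p = 9.42e-16, limma). Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), which encodes interferon γ, reached 4073 ± 292 (10.11 ± 0.47). Granzyme K, Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), averaged 2764 ± 892, a ratio of 8560 (1540 to 338000), although its annotated span encloses Esm1. Tox2 (10.73 ± 0.68), Sostdc1 (10.41 ± 0.93), Myo1f (10.33 ± 0.39), Ttc39c (10.34 ± 0.73), Asb2 (10.16 ± 0.40), Serpina3g (10.08 ± 0.40) and Cybb (ratio 2720, 932 to 13200) were also higher. Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392), an insulin-like growth factor binding protein gene of naive T cells, averaged 1410 ± 368 against 74430 ± 6282 (-5.76 ± 0.23). Tspan9 (-8.54 ± 1.23), Cd177 (-6.24 ± 1.03), Ldhd (-4.94 ± 0.61), Dapk1 (-4.92 ± 0.74) and Drc1 (-5.01 ± 0.86) were also lower. In total 2789 genes were higher in Teff and 1584 lower, of which 2048 and 603 by at least 2-fold. Quantile normalisation moved the median log2 fold change of all genes from 0.04 to -0.13 and the share of calls that were higher from 63.8% to 43.7%.

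Lists of activated and polarised T cells were called higher together. Several of these lists share members, such as Il10, Lag3 and Maf in the effector Treg and Tr1 lists, so their calls are not independent. Of 22 effector Treg genes 21 rose (22 adjusted over the list alone, camera adjusted p = 1.06e-23), including Tigit (5.84 ± 0.17) and Maf (6.47 ± 0.20). Of 22 Th1 and cytotoxic genes 20 rose and the perforin gene Prf1 fell (20 and 1 over the list alone, adjusted p = 3.3e-15), with Ccl5 (8.79 ± 0.36) and Nkg7 (7.50 ± 0.34) higher. Of 12 Tfh genes 11 rose (11, adjusted p = 4.93e-14), among them Cxcr5 (5.86 ± 0.17), the B cell follicle homing receptor, Pdcd1 (4.91 ± 0.17) and Il21 (8.51 ± 0.45). Th17 (8 of 10, 9 alone, adjusted p = 5.65e-08), Th2 (6 of 8, 6 alone, adjusted p = 1.03e-05), Tr1 (9 of 10, 10 alone, adjusted p = 2.74e-10), suppressive (11 of 12, 11 alone, adjusted p = 8.96e-13) and checkpoint genes (17 of 18, 17 alone, adjusted p = 9.86e-18) were higher too. Ccr6 was at least 619-fold higher, Il1r1 at least 310-fold and Il10 at least 185-fold. Of the Treg signature 16 of 19 rose and Foxp3 fell (16 and 2 alone, adjusted p = 4.39e-13), with Ctla4 (3.93 ± 0.12) and Nrp1 (5.82 ± 0.22) higher. Chemokine receptors rose (12 of 15, with Ccr7 lower, 12 and 1 alone, adjusted p = 3.69e-09), as did cell cycle genes (20 of 22, 20 alone, adjusted p = 1.27e-18), such as Rrm2 (3.59 ± 0.15) and Ccnb2 (6.22 ± 0.30). Naive and quiescence genes fell (14 of 19, 16 lower and 1 higher alone, adjusted p = 4.41e-14), with Lef1 (-2.09 ± 0.10) and Ccr7 (-1.80 ± 0.11). Markers of other cells moved with these groups: NK and NKT genes (9 of 11 higher, 9 alone, adjusted p = 7.64e-06), with Klrb1c, the gene of the NK-1.1 antigen, at least 500-fold higher. B cell genes (5 of 13 higher and Ighm lower, 6 and 1 alone, adjusted p = 0.00753) and myeloid genes (5 of 11 higher, 2 lower, 5 and 2 alone, adjusted p = 0.0293) were called higher as well. Some genes of plasmacytoid dendritic cells, chosen after their values were seen, were also higher: Siglech (7.39 ± 0.90, adjusted p = 1.27e-06, limma), Ly6d (6.18 ± 0.72) and Spib (4.98 ± 0.69). The lists of such genes were not tested in this comparison. Ly6d also averaged 252.4 ± 96.8 in resting Treg, where Siglech averaged 2.436 ± 0.722. The Tconv-high list was called lower (4 lower, 2 higher, the same counts alone, adjusted p = 0.0239), but its adjusted p was 0.16 after quantile normalisation, tried after the data were seen. Its lower genes, Igfbp4, Lef1, Satb1 and Dapl1, are all members of the naive and quiescence list too. Glycolysis genes were called higher (9 of 16, 9 alone), with an adjusted p = 0.294 with an estimated correlation. Integrins, egress, T cell receptor signal, heat shock, interferon, cholesterol synthesis (2 of 15 lower), platelet, basophil and mast, CD8 and γδ, and erythroid genes were not called as lists.

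CD49b-negative aTreg were compared with resting Treg to describe activation in the regulatory lineage. Klrg1 (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882), an inhibitory receptor of terminally differentiated T cells, rose from 12.4 ± 6.14 to 5772 ± 917 (8.87 ± 0.70, adjusted p = 2.31e-09, limma). Arnt2 (ENSMUSG00000015709, chromosome 7, 84246278 to 84410176) reached 961.6 ± 267 from 0 reads and was at least 1330-fold higher. Slc24a3, Srxn1 and Fgf16 were at least 792-fold, 598-fold and 557-fold higher. Ttc39c (8.73 ± 0.68), the transcription factor gene Cebpa (8.28 ± 0.66), Slc7a10 (8.79 ± 0.67), Ces2c (ratio 2680, 481 to 106000) and Cc2d2a (ratio 699, 239 to 3390) were also higher. Myo6 (ENSMUSG00000033577, chromosome 9, 80165031 to 80311729), an unconventional myosin gene, averaged 257.9 ± 31.1 against 10750 ± 615 (-5.38 ± 0.19, adjusted p = 1.32e-14, limma). Cnn3 (-5.06 ± 0.44), the prostaglandin receptor gene Ptger3 (-5.01 ± 0.65), Akr1c18 (-6.34 ± 0.80), Lhfp (-5.46 ± 0.86), Tlr5 (-5.45 ± 0.92), Spats2 (-5.39 ± 1.05), Tspan9 (-5.25 ± 1.14), Cd8a (ratio 185, 50.8 to 1530) and Arhgef10l (at least 81.6-fold) were lower. In total 3046 genes were higher in aTreg and 1888 lower, of which 1963 and 648 by at least 2-fold. Quantile normalisation moved the median log2 fold change of all genes from 0.05 to -0.11 and the share of calls that were higher from 61.7% to 44.2%.

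Of 22 effector Treg genes 20 rose (20 adjusted over the list alone, camera adjusted p = 1.97e-22), with the smallest p for Tigit (6.88 ± 0.16), Cxcr3 (7.52 ± 0.29), Ccr8 (4.79 ± 0.20) and Icos (3.43 ± 0.14). Cell cycle genes rose in 20 of 22 (21 alone, adjusted p = 1.54e-19), such as Rrm2 (3.46 ± 0.14) and Ccnb2 (5.76 ± 0.28). Checkpoint receptors (15 of 18, 16 alone, adjusted p = 5.99e-13), Tfh genes (11 of 12, 11 alone, adjusted p = 1.89e-10), Tr1 genes (9 of 10, 9 alone, adjusted p = 1.3e-10) and suppressive molecules (9 of 12, 9 alone, adjusted p = 5.33e-07) were called higher. So were chemokine receptors (10 of 15 higher and 2 lower, 11 and 2 alone, adjusted p = 1.93e-06), Th1 and cytotoxic genes (16 of 22 higher and 2 lower, 16 and 2 alone, adjusted p = 2.34e-06), Th2 (5 of 8, 5 alone, adjusted p = 0.0033), Th17 (6 of 10, 6 and 1 alone, adjusted p = 0.00789) and Treg signature genes (11 of 19 higher and 2 lower, 11 and 2 alone, adjusted p = 0.00323). Il10 rose by 8.27 ± 0.47, Fgl2 by 5.83 ± 0.31 and Ebi3 by 5.49 ± 0.33, all suppressive molecules, while Prf1 fell by 2.24 ± 0.18 and Eomes by 1.26 ± 0.35. Naive and quiescence genes fell in 16 of 19 (16 alone, adjusted p = 9.1e-16), among them the egress receptor S1pr1 (-2.36 ± 0.08), Satb1 (-2.89 ± 0.15) and Igfbp4 (-4.25 ± 0.22). The Tconv-high list was lower (6 of 10 lower and Id2 higher, the same counts alone, adjusted p = 0.00212), but all its lower genes except Pde3b are also naive and quiescence genes. Cholesterol synthesis genes fell in 14 of 15 (14 alone, adjusted p = 1.18e-11), with the squalene epoxidase gene Sqle at -1.93 ± 0.12 and Fdps at -1.38 ± 0.14. The CD8 and γδ list fell in all 5 genes (5 alone, adjusted p = 2.13e-06), with Tcrg-C1 down to 20.48 ± 5.92. Beside these, 9 of 13 B cell genes were higher (9 alone, adjusted p = 0.000233), including Cd22 (6.81 ± 0.34) and Ighm (1.46 ± 0.12). Glycolysis (10 of 16 higher, 2 lower, 11 and 2 alone) and erythroid genes (5 of 6 higher, 5 alone) were called higher, with adjusted p = 0.308 and 0.442 with an estimated correlation. Integrins (7 of 14 higher, 4 lower), egress (4 of 11 higher, 5 lower), T cell receptor signal, heat shock, interferon, platelet, and basophil and mast genes were not called as lists. Nor were myeloid genes (6 of 11 higher, 1 lower, camera adjusted p = 0.0614, fry 2.58e-07) and NK and NKT genes (4 of 11 higher, 1 lower), with Csf1r (6.52 ± 0.77) and Klrb1c (6.87 ± 0.60) higher. By fry, integrins (adjusted p = 8.85e-05) and NK and NKT genes (0.000917) were also called higher and egress genes lower (5.22e-09).

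CD49b-positive and CD49b-negative Teff were compared to ask what else differed with surface CD49b. Ccr10 (ENSMUSG00000044052, chromosome 11, 101172997 to 101175443), a chemokine receptor of skin-homing and mucosal lymphocytes, averaged 2629 ± 744 against 10.5 ± 11.04 (8.57 ± 0.70, adjusted p = 4.36e-08, limma). Itga1 (ENSMUSG00000042284, chromosome 13, 114953096 to 115101964), the collagen-binding integrin α1 subunit and a neighbour of Itga2, averaged 269.4 ± 118 against 4.08 ± 4.84 (6.13 ± 0.61). Itga2 itself rose by 3.64 ± 0.63 (adjusted p = 0.000391, limma). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), the IL-33 receptor gene, averaged 797.6 ± 416 against 61.9 ± 75.1 (4.28 ± 0.66). Pard3 (6.19 ± 0.85), the nuclear receptor gene Pparg (4.50 ± 0.44), Nmur1 (4.41 ± 0.64), Tmem255a (4.60 ± 0.72), Crybb1 (4.33 ± 0.57), Klra1 (4.84 ± 0.54; reads can be shared with other Klra genes) and Dkk3 (at least 84.6-fold) were higher. Sostdc1 (ENSMUSG00000036169, chromosome 12, 36314139 to 36318452), a BMP antagonist gene of the Tfh list, averaged 96.9 ± 87.8 against 4550 ± 2843 (-5.90 ± 0.86). Siglech (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925), a marker of plasmacytoid dendritic cells, averaged 23.4 ± 24.1 against 651.6 ± 192 (-5.50 ± 0.83). Ly6d (-5.26 ± 0.66), Edn3 (-5.96 ± 0.63), Gucy2g (-5.56 ± 0.73), Kdr (ratio 134, 36.7 to 1110), Cd209d (ratio 101, 34.2 to 491), Prss50 (ratio 94.2, 31.9 to 459), Flrt2 (at least 69.1-fold) and Rgs8 (at least 66.6-fold) were lower. Klra1, Kdr and Flrt2 were not called under DESeq2. In total 937 genes were higher in CD49b-positive Teff and 970 lower, of which 454 and 540 by at least 2-fold. Without resting Treg replicate 2 and CD49b-positive Teff replicate 1, a choice made after the data were seen, 1542 genes were higher. With library weights 2006 were higher and 1873 lower.

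The Tfh list fell in 11 of 12 genes (11 adjusted over the list alone, camera adjusted p = 1.57e-19), with Cxcr5 (-2.80 ± 0.15), Tox (-1.65 ± 0.12) and Pdcd1 (-2.05 ± 0.16). Checkpoint receptors fell in 10 of 18 (10 lower and 1 higher alone, adjusted p = 5.23e-08), among them Tnfrsf9 or 4-1BB (-1.88 ± 0.14) and Cd27 (-0.94 ± 0.09). Treg signature genes fell in 8 of 19, with 3 higher (9 and 4 alone, adjusted p = 0.00654). Cell cycle genes rose in 19 of 22 (22 alone, adjusted p = 1.5e-20), such as Rrm2 (1.78 ± 0.14) and Cdc20 (1.56 ± 0.16). Chemokine receptors rose in 8 of 15 and fell in 3 (11 and 3 alone, adjusted p = 0.000194), with Ccr8 (2.80 ± 0.20) and Ccr2 (3.82 ± 0.38) higher and Cxcr5, Cxcr4 and Ccr7 lower. Th2 genes rose in 4 of 8 (6 alone, adjusted p = 1.29e-05), Th17 genes in 4 of 10 (5 alone, adjusted p = 0.000137), with Tmem176b at 1.32 ± 0.16. Th1 and cytotoxic genes rose in 10 of 22 with 3 lower (11 and 3 alone, adjusted p = 0.00102). Of the last, Il18r1 (1.51 ± 0.24) and Runx3 (0.92 ± 0.14) were higher and Eomes (-3.61 ± 0.35), Gzmk and Prf1 lower. B cell genes were called lower beside these (5 of 13, 5 alone, adjusted p = 0.0072), including Ighm (-0.99 ± 0.12) and Cd74 (-1.53 ± 0.29, with overlapping libraries). Integrins (6 of 14 higher and Itgb8 lower, 6 and 2 alone) and interferon genes (Mx1 higher of 15, 0 alone) were called higher and T cell receptor signal genes (5 of 16 lower and 1 higher, 7 and 1 alone) lower with the preset correlation. Their adjusted p was 0.224, 0.471 and 0.175 with an estimated correlation. Tconv-high, effector Treg (9 of 22 higher, 5 lower), naive and quiescence, egress, Tr1, suppressive, heat shock, glycolysis, cholesterol synthesis, platelet, NK (3 of 11 higher, 3 lower), myeloid, basophil and mast, CD8 and γδ, and erythroid genes were not called as lists.

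The same comparison in aTreg asked what differed with CD49b among activated Treg. Ccr10 averaged 835.1 ± 255 in CD49b-positive aTreg against 15.9 ± 11.8 (5.96 ± 0.70, adjusted p = 1.7e-05, limma), and its neighbour Plekhh3 was at least 124-fold higher. Il1rl1, which marks a tissue-type Treg population, averaged 2281 ± 292 against 232.3 ± 108 (3.38 ± 0.66). Itga2 rose by 3.69 ± 0.63 (adjusted p = 0.000968, limma) and Itga1 from 2.14 ± 1.99 to 46.4 ± 5.47. The glucocorticoid-induced annexin gene Anxa1 (4.12 ± 0.63), the phospholipid transfer protein gene Pltp (3.34 ± 0.41), the Notch ligand gene Jag1 (4.27 ± 0.78), Sema6d (4.14 ± 0.77) and Erbb2 (3.43 ± 0.68) were also higher. Sostdc1 averaged 10.97 ± 9.74 against 358.9 ± 237 (-5.39 ± 0.86). Klrb1c (ENSMUSG00000030325, chromosome 6, 128778485 to 128789215) averaged 55.1 ± 15.01 against 405.2 ± 58.4 (-2.88 ± 0.60). Lypd6b (-4.47 ± 0.63), Plxdc2 (-4.21 ± 0.65), Scin (-3.77 ± 0.61), Arhgap20 (-3.15 ± 0.59), Btk (-3.11 ± 0.87), Fam110c (-3.06 ± 0.82), Sptb (-2.99 ± 0.83) and Car11 (-2.93 ± 0.33) were lower. Btk and Sptb were not called with a pseudocount of 0.5, nor Fam110c under edgeR or DESeq2. In total 452 genes were higher in CD49b-positive aTreg and 415 lower, of which 163 and 156 by at least 2-fold. Without resting Treg replicate 2 and CD49b-positive Teff replicate 1, left out after the data were seen, 1050 were higher and 815 lower. Neither library is in the groups compared, so the fold changes stayed the same and only the spread pooled over all 6 groups changed. Without CD49b-positive aTreg replicate 2 alone, 283 were higher and 237 lower, and with library weights 1612 and 1493.

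Effector Treg genes were called higher (7 of 22 rose and Pdcd1 fell, 13 and 3 adjusted over the list alone, camera adjusted p = 9.55e-05), with Ccr2 (2.35 ± 0.38), Fgl2 (1.82 ± 0.31) and Prdm1 or Blimp-1 (1.01 ± 0.20). Th1 and cytotoxic genes rose in 8 of 22 and fell in 2 (11 and 2 alone, adjusted p = 4.59e-07), with Gzmk (2.19 ± 0.34) and Runx3 (0.93 ± 0.14) higher and Eomes (-2.63 ± 0.35) and Fasl lower. Egress genes rose in 3 of 11 (6 higher and 1 lower alone, adjusted p = 9.55e-05), namely S1pr1 (0.95 ± 0.08), Klf2 (0.84 ± 0.21) and Selplg (0.47 ± 0.09). Cholesterol synthesis genes rose in 9 of 15 (10 alone, adjusted p = 1.3e-10), among them Cyp51 (0.61 ± 0.10), Hmgcs1 (0.90 ± 0.16) and Sqle (0.63 ± 0.12). Tfh genes fell in 7 of 12 (10 alone, adjusted p = 2.65e-11), including Cxcr5 (-1.03 ± 0.15) and Bcl6 (-1.28 ± 0.22). Chemokine receptors rose in 5 of 15 and fell in 3 (6 and 3 alone, adjusted p = 0.0117). Their adjusted p was 0.0528 without the libraries named above, which lie outside the groups compared. Naive and quiescence genes (7 of 19 lower and 2 higher, 8 and 3 alone) and T cell receptor signal genes (3 of 16 lower, 6 alone) were called lower with the preset correlation, with adjusted p = 0.0565 and 0.0756 with an estimated correlation. Ccr7 fell by 1.43 ± 0.10, Tcf7 by 1.27 ± 0.14 and Egr2 by 1.36 ± 0.17. Cell cycle (5 of 22 higher, 10 alone), Th2 (2 of 8, 3 alone), interferon (1 of 15, 8 alone) and integrin genes (4 of 14 higher and Itga5 lower, 5 and 1 alone) were called higher, and erythroid genes lower (Hba-a1 of 6, 5 alone). Their adjusted p was 0.0838, 0.0822, 0.219, 0.202 and 0.129 with an estimated correlation. The integrin list had a median of -0.02 and a mean of 0.38, against a test for higher values. Treg signature, Tconv-high, Th17, Tr1, suppressive, checkpoint (2 of 18 higher, 4 lower), heat shock, glycolysis, platelet, NK, B, myeloid, basophil and mast, and CD8 and γδ genes were not called as lists.

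**Figure D4:**
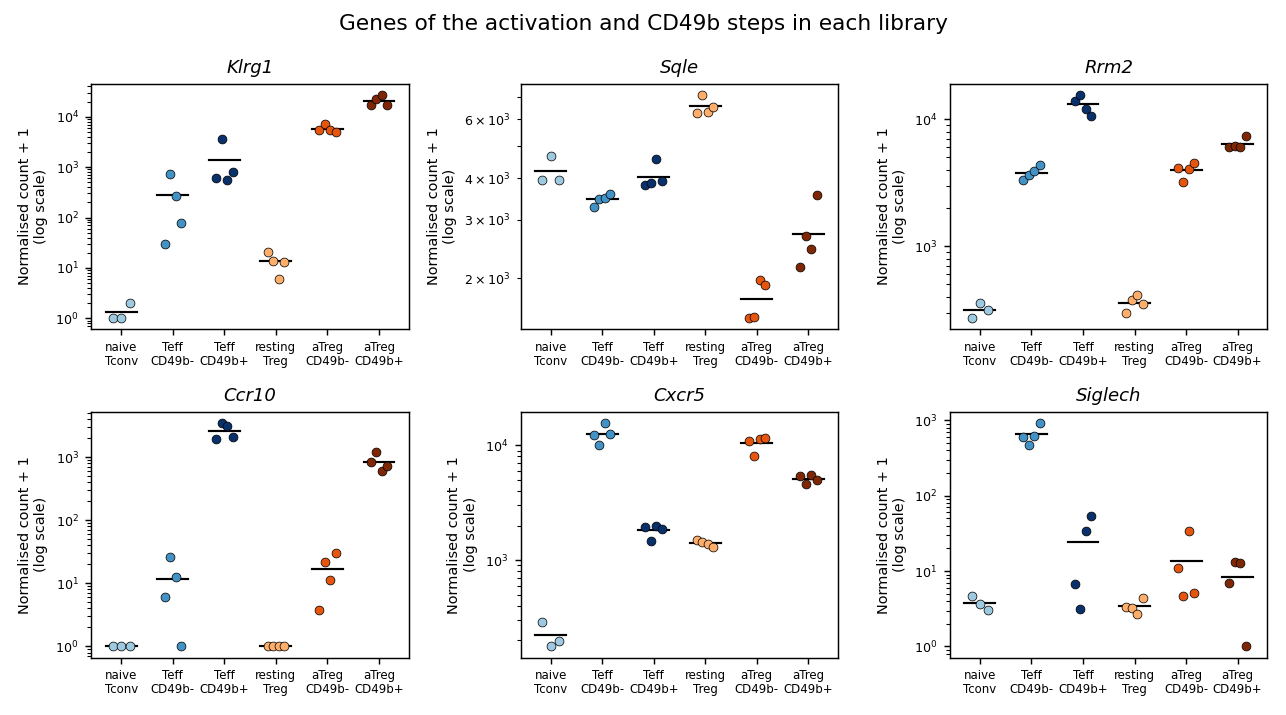
Normalised read count plus 1 (log axis) of Klrg1, Sqle, Rrm2, Ccr10, Cxcr5 and Siglech in each of the 23 libraries, arranged by the 6 groups, with points for libraries and a line at each group mean. Ccr10 averages 2629 and 835.1 in CD49b-positive Teff and aTreg against 10.5 and 15.9 in the CD49b-negative groups, and Siglech averages 651.6 in CD49b-negative Teff against 23.4 in CD49b-positive Teff.

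Lineages were next compared within the CD44-high CD49b-negative state. Besides Foxp3 (11.76 ± 0.51), Lrrc32 was higher in aTreg than in Teff (11.33 ± 0.50, adjusted p = 5.87e-13, limma), as were Fcmr (8.09 ± 0.68), the IgM Fc receptor gene, Atp6v0d2 (7.98 ± 0.92), Sh3bgrl2 (7.60 ± 0.91), Stra6 (7.57 ± 0.74) and Cables1 (7.34 ± 0.70). The neutrophil-attracting chemokine gene Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) averaged 456.2 ± 57.3 in aTreg (ratio 922, 255 to 7620) and Ky 463.7 ± 94.5 (ratio 625, 213 to 3030). Flicr (6.99 ± 0.43) overlaps Foxp3 on chromosome X and cannot be told from it without strand information. Gzmk averaged 8.57 ± 5.41 in aTreg against 2764 ± 892 (-8.29 ± 0.34). The phosphodiesterase gene Pde3b (ENSMUSG00000030671, chromosome 7, 114415281 to 114539251) averaged 29.0 ± 24.2 against 5289 ± 1333 (-8.23 ± 1.02). Esm1 (-8.15 ± 0.55), which lies within the annotated span of Gzmk, osteopontin Spp1 (-8.11 ± 0.88), Smoc2 (-7.89 ± 0.53), Ryr1 (-7.27 ± 0.71), Chn1 (-7.15 ± 0.66), St6galnac1 (-6.75 ± 0.63), Lpar3 (ratio 348, 96 to 2880) and Edn3 (ratio 325, 111 to 1580) were also lower. In total 2002 genes were higher in aTreg and 1634 lower, of which 989 and 864 by at least 2-fold. Without the 2 libraries farthest from their groups, left out after the data were seen, 2872 genes were lower. Neither is in the groups compared, so only the spread pooled over all 6 groups changed. With library weights 3410 were higher and 3282 lower.

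Of the Treg signature 18 of 19 were higher (19 adjusted over the list alone, camera adjusted p = 7.63e-26), with Ctla4 at 2.90 ± 0.11 and Tnfrsf9 at 3.74 ± 0.14. All 10 Tconv-high genes were lower (10 alone, adjusted p = 1.25e-14), with Il2 at -5.23 ± 0.30. Effector Treg genes were higher in 16 of 22 and Cxcr3 was lower (17 and 2 alone, adjusted p = 5.41e-13), with Ccr8 (4.89 ± 0.20), Prdm1 (2.97 ± 0.20) and Il10 (4.25 ± 0.47). Suppressive (9 of 12, 11 alone, adjusted p = 9.29e-11), checkpoint (10 of 18 higher, 3 lower, 11 and 3 alone, adjusted p = 1e-06), Tr1 (5 of 10 higher, 1 lower, 6 and 1 alone, adjusted p = 0.000683) and Th2 genes (5 of 8 higher, 6 alone, adjusted p = 0.00459) were called higher, although the Th2 cytokine gene Il4 was lower (-4.56 ± 0.47). Th1 and cytotoxic genes were lower in 15 of 22 and higher in 3 (16 and 3 alone, adjusted p = 2.13e-06), with Fasl (-1.80 ± 0.13) and Il18r1 (-2.52 ± 0.24) lower. NK and NKT genes were lower in 8 of 11 (10 alone, adjusted p = 3.86e-07), with Klrk1 at least 115-fold lower and Eomes at -3.87 ± 0.35. Naive and quiescence genes were lower in 14 of 19 and higher in 3 (the same counts alone, adjusted p = 4.37e-07). Egress genes were lower in 5 of 11 (5 lower and 1 higher alone, adjusted p = 0.00273), with S1pr1 at -1.87 ± 0.07 and S1pr5 at least 125-fold lower. T cell receptor signal genes (7 of 16 higher, 1 lower, the same counts alone) were called higher and cholesterol synthesis genes (11 of 15 lower, 11 alone) lower with the preset correlation. Their adjusted p was 0.325 and 0.0699 with an estimated correlation. Of 13 B cell genes 5 were higher and 2 lower without a list call (adjusted p = 0.103), with Ighm at 183700 against 40040. Some genes of plasmacytoid dendritic cells, chosen after their values were seen, were lower in aTreg: Siglech (-6.03 ± 0.83, adjusted p = 1.2e-05, limma), Ly6d (-5.59 ± 0.66) and Spib (-3.20 ± 0.64). Others were not: Irf8 was called higher (0.76 ± 0.18), and Tcf4 and Upb1 were not called. The lists of such genes were not tested in this comparison. Integrin, chemokine receptor, Th17, Tfh, cell cycle, heat shock, interferon, glycolysis, platelet, myeloid, basophil and mast, CD8 and γδ, and erythroid genes were not called as lists.

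In the CD44-high CD49b-positive state, Foxp3 (12.54 ± 0.51) and Lrrc32 (9.13 ± 0.50, adjusted p = 1.18e-11, limma) were again higher in aTreg than in Teff. Ky (ENSMUSG00000035606, chromosome 9, 102505750 to 102546239) averaged 956.8 ± 76.5 and was at least 1200-fold higher, C78197 at least 1230-fold. Fcmr (9.51 ± 0.68), the coagulation factor gene F13a1 (8.01 ± 0.91), Slc7a10 (7.77 ± 0.67), Cxcl2 (7.47 ± 0.73) and Fgf16 (7.35 ± 0.64) were also higher. The ADP receptor gene P2ry1 (ENSMUSG00000027765, chromosome 3, 61002795 to 61008982) averaged 882.7 ± 120 in Teff and was at least 1230-fold lower in aTreg, Aqp9 at least 616-fold and Smoc2 at least 437-fold. Klrk1 (ENSMUSG00000030149, chromosome 6, 129610323 to 129623864), which encodes the NK receptor NKG2D, averaged 9.03 ± 7.97 against 861.4 ± 152 (-7.05 ± 0.66). Pde3b (-7.94 ± 1.02), Ryr1 (-7.69 ± 0.71), Lypd6b (-7.12 ± 0.63), St6galnac1 (-7.20 ± 0.63), S1pr5 (ratio 749, 256 to 3640) and Ggt5 (ratio 619, 171 to 5110) were also lower. In total 2487 genes were higher in aTreg and 1932 lower, of which 1341 and 909 by at least 2-fold. With library weights 3193 were lower.

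Treg signature genes were higher in 18 of 19 (18 adjusted over the list alone, camera adjusted p = 1.06e-23), all 10 Tconv-high genes lower (10 alone, adjusted p = 4.7e-15) and all 12 suppressive molecules higher (12 alone, adjusted p = 2.91e-12), with Ctla4 (3.97 ± 0.11), Il10 (6.67 ± 0.47) and Areg (4.07 ± 0.37). Effector Treg (18 of 22, 20 and 1 alone, adjusted p = 8.92e-14), checkpoint (13 of 18 higher, 3 lower, the same counts alone, adjusted p = 1.13e-09) and Tr1 genes (8 of 10 higher, 1 lower, the same counts alone, adjusted p = 6.19e-05) were called higher. Naive and quiescence genes were lower in 15 of 19 and higher in 3 (16 and 3 alone, adjusted p = 4.53e-08), with Tcf7 at -2.88 ± 0.14. Th1 and cytotoxic genes were lower in 14 of 22 and higher in 3 (14 and 4 alone, adjusted p = 0.000121). NK and NKT genes were lower in 9 of 11 (9 alone, adjusted p = 7.29e-08), with Zbtb16 at -5.71 ± 0.71. Cell cycle genes were lower in 15 of 22 (19 alone, adjusted p = 5.33e-07), such as Rrm2 (-1.02 ± 0.14) and Pcna (-0.72 ± 0.11). B cell genes were called higher (5 of 13 and Cd22 lower, 5 and 1 alone, adjusted p = 0.0142), with Ighm at 3.17 ± 0.12 and Cd74 at 3.04 ± 0.29. Tfh (6 of 12 higher, 2 lower, 8 and 2 alone) and T cell receptor signal genes (6 of 16 higher, 2 lower, 8 and 2 alone) were called higher. Called lower were egress (3 of 11 lower, 1 higher, the same counts alone), Th17 (4 of 10 lower, Ccr6 higher, 4 and 2 alone) and CD8 and γδ genes (3 of 5 lower, 1 higher, the same counts alone). For these 5 lists in order, adjusted p was 0.17, 0.33, 0.0534, 0.078 and 0.206 with an estimated correlation. Integrin, chemokine receptor, Th2, heat shock, interferon, glycolysis, cholesterol synthesis, platelet, myeloid, basophil and mast, and erythroid genes were not called as lists.

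Whether the CD49b step differed between lineages was tested as an interaction, the log2 change in Treg minus that in Tconv. Across all genes tested the steps correlated at Pearson r = 0.397 (Spearman rho = 0.41). This is a correlation across genes, which are not independent replicates. No library was shared. Of the genes called in each lineage, 252 were higher in both, against 27 for independent lists, and 203 were lower in both, against 25.6, while 7 and 5 were called in opposite directions. The interaction was called for 160 genes with the higher and 119 with the lower value in Treg (230 lower without the 2 libraries farthest from their groups, 77 without CD49b-positive aTreg replicate 2, and 498 and 483 with library weights). Ccr8 had the more negative step in Treg (-2.89 ± 0.28, adjusted p = 1.18e-05, limma). Ly6d (5.95 ± 0.94), Ctsh (5.90 ± 0.92), Cxcr5 (1.77 ± 0.22), Tox (1.48 ± 0.16) and Tnfrsf9 (1.48 ± 0.20) had the more positive. Ly6d was lower with CD49b in Teff (-5.26 ± 0.66), as were Siglech (-5.50 ± 0.83) and Spib (-3.98 ± 0.64), and was not called in aTreg (0.70 ± 0.66). Tfh (4 of 12 more positive, 6 adjusted over the list alone, camera adjusted p = 1.63e-11), checkpoint (5 of 18 more positive, 1 more negative, 10 and 1 alone, adjusted p = 7.11e-10), cholesterol synthesis (1 of 15, 5 alone, adjusted p = 6.17e-06), Treg signature, B cell and myeloid genes had called positive differences. Cell cycle (3 of 22 more negative, 12 alone, adjusted p = 2.61e-15), Tconv-high, Th2 and Th17 genes had negative ones. Chemokine receptor, suppressive, glycolysis, CD8 and γδ, and erythroid lists were called only with the preset correlation, with adjusted p = 0.115, 0.0893, 0.484, 0.0731 and 0.208 with an estimated correlation.

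**Figure D5:**
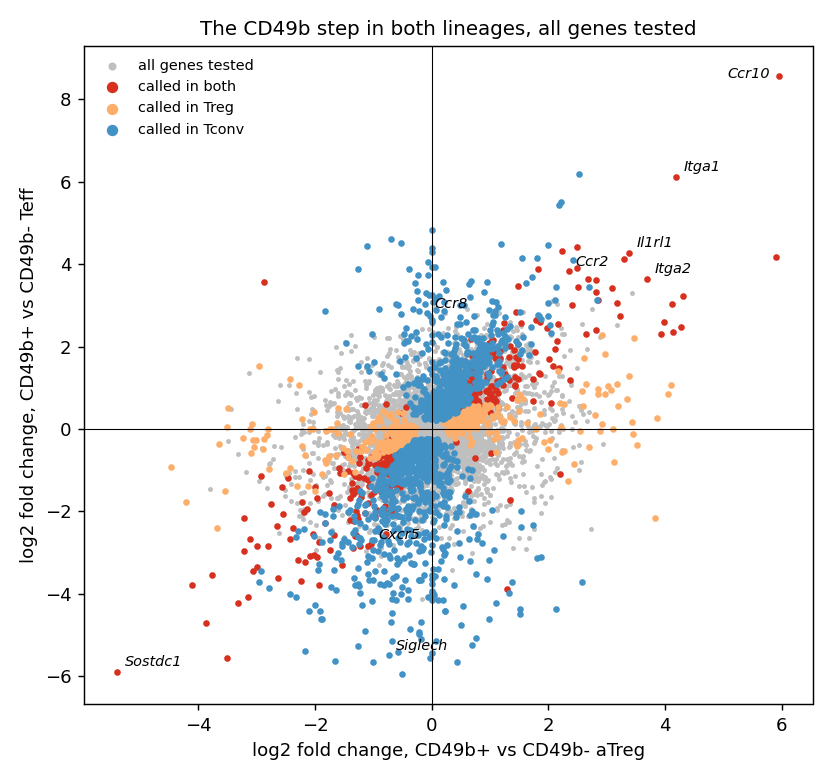
Log2 fold change of CD49b-positive over CD49b-negative cells in aTreg (horizontal) against Teff (vertical), 1 point per gene for 15704 genes, coloured by whether the gene was called in both lineages, in Treg, in Tconv or in neither. Ccr10 lies at 5.96 and 8.57 and Sostdc1 at -5.39 and -5.90.

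The activation step was tested in the same way. Its changes in both lineages correlated across genes at r = 0.665 (rho = 0.589), with 1842 genes higher in both against 541 for independent lists, 838 lower in both against 190, and 43 and 55 in opposite directions. The interaction was called for 520 genes with the higher and 876 with the lower value in Treg (1011 and 1382 without the 2 libraries farthest from their groups, 807 higher without resting Treg replicate 2, and 1153 and 1463 with library weights). Cxcr5 (-2.96 ± 0.22), Ctla4 (-2.39 ± 0.16), Nrp1 (-4.75 ± 0.29), Ifng (-5.35 ± 0.65, adjusted p = 7.21e-06, limma), Nkg7 (-5.21 ± 0.46), Il21 (-6.66 ± 0.61) and Kcnk5 (-10.59 ± 0.89) had the smaller or more negative step in Treg. Ccr8 (2.52 ± 0.29) and Prdm1 (2.22 ± 0.30) had the larger. Treg signature (11 of 19 more negative and Foxp3 more positive, 14 and 1 adjusted over the list alone, camera adjusted p = 9.73e-15), Th1 and cytotoxic (11 of 22, 13 alone, adjusted p = 1.26e-11) and cholesterol synthesis genes (10 of 15, 12 alone, adjusted p = 7.67e-11), the latter with Sqle at -1.65 ± 0.18, had more negative steps in Treg. Chemokine receptor, egress, Th17, Tfh, suppressive, checkpoint, NK and NKT, and CD8 and γδ lists were also called more negative, while the Th2 list had an adjusted p = 0.129 with an estimated correlation. Foxp3, a gate gene, was called lower in Tconv activation from a low level and was not called in Treg activation.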

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

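Tests of B cell RNA, of GC content and length on single libraries, and of a wrong group label were chosen only after the result was seen.

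Genes of plasmacytoid dendritic cells were lower in CD49b-positive than in CD49b-negative Teff. On a first list, seen beforehand, 10 of 12 genes were lower with a median log2 fold change of -3.98, and on a second list, not looked at before, 8 of 14 were lower and 1 higher with a median of -1.35. RNA of plasmacytoid dendritic cells in the CD49b-negative Teff libraries is a candidate explanation, as a hypothesis only, although the TCRβ gate would remove such cells. Of the 26 genes on both lists 18 were called lower, and 5 were above 300 normalised counts in naive Tconv, so that T cells also express them. Of the 18 called lower, 15 were not above that level there. Not every gene that was low in naive Tconv fell with CD49b. Klk1b27 averaged 0.3018 in naive Tconv, 368.6 in CD49b-negative Teff and 278.6 in CD49b-positive Teff, and was not called lower. RNA of B cells stays open, since lineage genes had a median of -0.44 with 0 of 4 called while the fixed B cell list was called lower (5 of 13, camera adjusted p = 0.0072), as does expression by the T cells themselves.

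Resting Treg replicate 2 and CD49b-positive Teff replicate 1 stood apart from their groups, with an SD of deviations from the other libraries of 1.09 and 0.913 on the log2 scale, 1.35 and 1.26 times the highest of the other libraries of the group. After a trend with GC content and length was removed, these were 0.961 and 0.834, or 1.26 and 1.16 times. The test was void, since both ratios already lay below its upper bound before the trend was removed, so that for neither library can such a bias be told apart from other causes. A wrong group label was argued against, since 0 of the 2 correlated best with another group.

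Cholesterol synthesis genes were lower in CD49b-negative aTreg than in resting Treg, with a median log2 fold change of -0.95 over 15 genes. The median was -1.28 after a trend with GC content and length was removed and -0.93 without resting Treg replicate 2, which argues against both as the whole cause. A change of cholesterol synthesis with Treg activation remains a hypothesis, and other explanations were not tested.

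Of 109 sets of group values tested with the Dixon test for a sample far from the others, 7 passed, and chance gives about 1 in 20. Foxp3 in CD49b-positive Teff was 36.24 in replicate 2 against 3.414 to 7.127 in the others. Itga2 in CD49b-positive aTreg was 641.5 in replicate 4 against 541.2 to 548.3. P2ry1 in CD49b-positive Teff was 1062 in replicate 3 against 804.8 to 833. Ighm in CD49b-positive aTreg was 196900 in replicate 3 against 175600 to 177200, and Ighj1 in CD49b-negative aTreg was 1687 in replicate 2 against 1921 to 1943. Igha in CD49b-positive aTreg was 4504 in replicate 1 against 0 to 4.823. The mitochondrial share in CD49b-negative aTreg was 1.461% in replicate 2 against 0.7122% to 0.8014%.

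The CD49b step differed between lineages for 160 genes with the higher and 119 with the lower value in Treg, tested as an interaction. By size these were Sort1 (6.30 ± 1.61), Ly6d (5.95 ± 0.94), Ctsh (5.90 ± 0.92), Tmem255a (-5.30 ± 1.02) and Sh3bgrl2 (-5.16 ± 1.29). Genes with near-zero groups are given by the mean of the highest of the 4 groups compared: Kdr (69 in CD49b-negative Teff), Lmo7 (95.7 in CD49b-positive aTreg), and Ptger3 (29.48), Hc (52.76) and Klra1 (70.86) in CD49b-positive Teff. Calls for Sort1, Sh3bgrl2, Kdr, Lmo7, Klra1, Hc and Cdc20 ended under at least 1 alternative. Further genes were Ccr8 (-2.89 ± 0.28), Tnfrsf9 (1.48 ± 0.20), Tox (1.48 ± 0.16), Cxcr5 (1.77 ± 0.22), Rrm2 (-1.09 ± 0.19), Cdc20 (-0.90 ± 0.22), Ctla4 (1.07 ± 0.15) and S1pr1 (0.86 ± 0.11). Lists called with both correlations differed with median log2 of 0.28 (Treg signature), -0.43 (Tconv-high), -1.09 (Th2), -0.71 (Th17), 0.89 (Tfh), 0.90 (checkpoint), -0.78 (cell cycle), 0.41 (cholesterol synthesis), 0.58 (B cell) and 0.65 (myeloid).

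The activation step differed between lineages for 520 genes with the higher and 876 with the lower value in Treg. By size these were Stard8 (8.23 ± 1.74), Ly6d (-11.18 ± 0.98), Kcnk5 (-10.59 ± 0.89) and Syk (-8.77 ± 1.25). Among the 4 groups compared, means of the highest were 463.7 (Ky), 63.77 (Rbm24), 456.2 (Cxcl2) and 410.4 (Fgf16) in CD49b-negative aTreg, 806.9 for Spp1 in CD49b-negative Teff and 58.24 for Arhgef10l in resting Treg. Ky, Cxcl2 and Fgf16 were not called under edgeR. Further genes were Sqle (-1.65 ± 0.18), Fdft1 (-1.09 ± 0.18), Ifng (-5.35 ± 0.65), Nkg7 (-5.21 ± 0.46), Nrp1 (-4.75 ± 0.29), Socs2 (-5.19 ± 0.24), S1pr1 (-1.71 ± 0.11), Ccr8 (2.52 ± 0.29), Prdm1 (2.22 ± 0.30), Il2 (-5.10 ± 0.44) and Il21 (-6.66 ± 0.61). Lists called with both correlations differed with median log2 of -1.94 (Treg signature), -0.89 (chemokine receptors), -0.86 (egress), -2.25 (Th1 and cytotoxic), -2.09 (Th17), -1.92 (Tfh), -1.67 (suppressive), -1.17 (checkpoint), -0.90 (cholesterol synthesis), -3.02 (NK and NKT) and -8.15 (CD8 and γδ). With genes at 3 or fewer reads set to the floor, the Tfh, suppressive and NK medians were -1.87, -1.97 and -2.66.

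No other split or labelling tried gave as many calls as the real one. With 35 splits the share cannot fall below 1 in 35 for a comparison. Chance is thus argued against but not excluded. Of the 35 splits of the libraries of each pair of groups, only 1, the real split, gave as many genes: 4934 against at most 1690 elsewhere for activation in Treg, 867 against 3 for the CD49b step in Treg, 4373 against 2346 for activation in Tconv and 1907 against 16 for the CD49b step in Tconv. For lineage the real counts were 3661, 3636 and 4419 in the CD62L-high, CD49b-negative and CD49b-positive states, against at most 3117, 2 and 128. For the differences in steps, lineage labels were redrawn within each state with lineage means removed, giving 100 labellings with the real one included. The real labels gave 279 against at most 2 for the CD49b step and 1397 against at most 238 for activation. The 1397 stands beside 1396 in the report, whose fit keeps the lineage means.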

How the results depend on the processing

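Leaving out resting Treg replicate 2 and CD49b-positive Teff replicate 1 together, and quantile normalisation of the list tests, were tests chosen only after the result was seen. No named gene called in the report or under an alternative run on genes reversed its direction there. No called list did under the 6 run on lists, but the balance of calls did under quantile normalisation. Directions of genes called in neither fit were not compared. Causes were not tested unless stated.

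Under edgeR, TMM normalisation, a pseudocount of 0.5, no filter and a filter at 50, all 18 counts of calls stayed within 1.5 times. edgeR and the report shared 4653 calls for activation in Treg, 792 for the CD49b step in Treg and 200 for the difference in CD49b steps. Quantile normalisation, which forces all libraries to the same distribution, gave 2395 genes higher and 3027 lower for activation in Treg (3046 and 1888 in the report) and 2177 and 2810 in Tconv (2789 and 1584). For the CD49b step in aTreg it gave 437 and 502 (452 and 415). For the CD49b step in aTreg (452 and 415), only the compared groups gave 1100 and 777, library weights 1612 and 1493, DESeq2 732 and 693, and leaving out both libraries 1050 and 815. For the CD49b step in Teff (937 and 970), weights gave 2006 and 1873, and leaving out both libraries 1542 higher. For lineage, only the compared groups gave 1241 and 589 in the CD62L-high state and 2484 lower in the CD49b-negative state. Weights gave 3410 and 3282 in the CD49b-negative state and 3193 lower in the CD49b-positive state, and leaving out both libraries 2872 lower in the CD49b-negative state. Neither library is in the groups of that comparison or of the CD49b step in aTreg. There the fold changes stayed the same and only the pooled spread changed. For the difference in CD49b steps (160 and 119), a pseudocount of 8 gave 246 and 188, only the compared groups 201 lower, weights 498 and 483, DESeq2 267 and 258, and leaving out both libraries 230 lower. For the difference in activation steps (520 and 876), weights gave 1153 and 1463 and leaving out both libraries 1011 and 1382.

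With single libraries left out, the CD49b step in aTreg gave 283 to 402 genes higher and 237 to 396 lower, both lowest without CD49b-positive aTreg replicate 2, and 263 and 270 lower without CD49b-negative aTreg replicates 1 and 4. The CD49b step in Teff gave 644 lower (without CD49b-negative Teff replicate 3) to 968. The difference in CD49b steps gave 77 lower (without CD49b-positive aTreg replicate 2) to 148, with 79 without CD49b-negative Teff replicate 1 and CD49b-negative aTreg replicates 1 or 4. The difference in activation steps gave 394 to 807 higher, the latter without resting Treg replicate 2. A smaller group lowers the number of calls by itself.

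The correlation of steps between lineages was 0.515 for the CD49b step and 0.727 for activation with the filter at 50, which removes low genes, and 0.653 for activation without both libraries.

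Of the list tests 213 of 243 kept their side of the threshold with an estimated correlation and 30 lost their call, the latter given in the report. Under fry 3 calls were lost, for glycolysis (adjusted p = 0.329, range over alternatives 0.0304 to 0.484) and erythroid genes (0.0985, range 0.00114 to 0.208) in the difference of CD49b steps and interferon genes in the CD49b step of Teff (0.151, range 0.012 to 0.471). Fry also called 35 list tests that were not called in the report. Calls were gained elsewhere too, 4 with no filter, 3 under quantile normalisation and 5 without both libraries. Under TMM 2 were lost, for chemokine receptors in the difference of CD49b steps (0.0616, range 0.0381 to 0.115) and erythroid genes in Treg activation (0.0516, range 0.00616 to 0.442). Quantile normalisation ended 10 calls, among them Tconv-high genes in Tconv activation (0.16, range 1.03e-09 to 0.16). Leaving out both libraries ended 9, among them chemokine receptors in the CD49b step of aTreg (0.0528, range 0.00298 to 0.0528), whose groups hold neither library.

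Of the 720 results for named genes, 18 lost their call under edgeR, 15 under DESeq2, 16 with only the compared groups, 9 and 7 with pseudocounts of 0.5 and 8, 8 under quantile normalisation, 2 each with weights, with no filter and without both libraries, and 1 under TMM. With single libraries left out, 253 of 6337 did. Among genes printed with values, in the CD49b step of aTreg, calls ended for Fam110c under edgeR and DESeq2 and for Btk and Sptb with a pseudocount of 0.5. Under DESeq2 they ended for Klra1, Flrt2 and Kdr in the CD49b step of Teff and for Dmbt1 between lineages in the CD62L-high state. In the difference of CD49b steps they ended for Sort1, Kdr and Klra1 under edgeR and DESeq2, Lmo7 under edgeR, Sort1, Lmo7 and Sh3bgrl2 with a pseudocount of 0.5, and Cdc20 under quantile normalisation. In the difference of activation steps they ended for Ky, Cxcl2 and Fgf16 under edgeR. Leaving out a single library also ended calls for Klf2, Btk, Sptb and Fam110c in the CD49b step of aTreg and for Sort1, Lmo7, Sh3bgrl2, Hc and Cdc20 in the difference of CD49b steps.

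A replicate block changed no count by over 1.5 times, with 447 and 393 genes for the CD49b step in aTreg and 147 and 99 for the difference in CD49b steps. Under the block 11 of the 720 results for named genes lost their call, among them Sort1, Lmo7, Sh3bgrl2 and Cdc20 in the difference of CD49b steps. Samples sharing only a number had a mean correlation of deviations of 0.011 over 55 pairs, from -0.204 to 0.112, against -0.004 over 165 other pairs. With its own number 9 of 23 libraries correlated best.

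Depth limits genes with few reads: in groups with 0 reads only a floor on the fold can be given. Separately, 2-fold changes were called for 39% to 73% of simulated genes with a mean of at least 50. Genes with a lower mean were not changed in the simulation.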

Other observations

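Antigen receptor and NK receptor genes outside the gates of the sort were measured. Klrb1c, which encodes the NK-1.1 antigen gated against, averaged 465 ± 52.5 normalised counts in CD49b-negative Teff, 340.6 ± 110 in CD49b-positive Teff, 405.2 ± 58.4 in CD49b-negative aTreg and 55.1 ± 15.01 in CD49b-positive aTreg. Ighm, the immunoglobulin μ constant gene, averaged 53990 in naive Tconv, 40040 and 20550 in CD49b-negative and CD49b-positive Teff, 67080 in resting Treg, and 183700 and 181600 in CD49b-negative and CD49b-positive aTreg. Ighj1 averaged 1869 and 1606 in the aTreg groups against 39.5 and 2.865 in the Teff groups. Ighg3 averaged 266.3 in CD49b-negative aTreg, 67.0 in CD49b-positive aTreg and 0 in resting Treg. Hba-a1, an α-globin gene near-identical to Hba-a2, averaged 5.343 ± 2.76, 46.8 ± 6.91 and 5.685 ± 3.70 in resting, CD49b-negative and CD49b-positive Treg.

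Among T cell receptor γ genes, which can share reads, Tcrg-C1, Tcrg-C2 and Tcrg-C4 averaged 1030, 394.5 and 688.4 in resting Treg, against 6.132, 1.207 and 0 in naive Tconv and 20.48, 10.24 and 25.06 in CD49b-negative aTreg. In CD49b-positive Teff, Tcrg-C1 averaged 96.6 and Tcrg-C4 170.3.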
